A study of Xenopus laevis with 20 samples.

How the data were processed

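ChIP-seq libraries had been made from Xenopus laevis embryos at stage 20, from whole embryos and from foregut and hindgut explants. The 20 samples fell into 20 groups of 1 library, 10 of them inputs, and the groups were taken from the sample titles. The 4 deposited peak lists were used as single lists: Smad1 and p300 in whole embryos, with 1 ChIP library each in the labels, and β-catenin and p300 in explants, with 4 each.

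FastQC, Trimmomatic, Bowtie2, Picard, SAMtools and MACS2 are named in the submitters' processing notes, without versions or roles. The genome build is not given in the sources used here. The lists have the column layout of MACS2 narrow peaks, with no header. Each peak has a position, a score, a fold enrichment, the −log10 of a p-value and of a q-value, and the distance of the summit from the start. The fold is a ratio of ChIP pileup over local background as the authors deposited it. In the β-catenin, Smad1 and explant p300 lists the authors' score is 10 times the −log10 p-value, to within 1 unit, in each peak, the peaks are ordered by it, and the lists end at a −log10 p of 78.6, 14.4 and 23.1. The titles of these 3 deposited lists name IDR (irreproducible discovery rate), whose settings are not given in the sources used here. The numbers in their peak names run to 195449, 31255 and 96602, so that the deposited lists hold at most 8.34%, 25.5% and 15.7% of the peaks so numbered. In the whole-embryo p300 list the deposited score is 10 times the −log10 q-value, the lowest −log10 q is 1.30, and its title names no IDR. Its intervals with several summits appear on 172 repeated lines, and it gives no summit on 14 lines. By the peak names in the deposited lists, β-catenin and explant p300 peaks were called on pooled foregut and hindgut, DMSO and BIO libraries against a control. The Smad1 peak names also name a pooled experiment against a control, although the labels give 1 Smad1 ChIP library. The antibody is named Smad in the labels and phosphorylated Smad1 in the peak names, and it is called Smad1 here.

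An interval with several summits was kept once, with its highest score. A peak without a summit was given its midpoint. Peaks overlapped if they shared at least 1 bp. The overlap of a pair of lists was compared with 1000 placements of the first list at random positions within the same chromosome or scaffold, each taken to reach as far as the last peak of any list. The result is given as the fold over the mean of the placements with a one-sided permutation p. Peaks on short scaffolds fall on each other in such placements, which lowers the fold. p300 overlap at peaks with and without a partner was compared by odds ratio and a two-sided Fisher's exact test, and scores by the probability of the higher score with a two-sided permutation test of 100000 resamples. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Peaks are not replicates and neighbouring peaks are not independent, so the tests describe the lists. The threshold of each test was 0.05. Read counts and depth per sample are unknown, and depth therefore gives no interval here.

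Peaks named in the report as the strongest of a list or among the joint sites were chosen by a rule set before the data were examined: the 3 highest scores of each list, and the 10 highest-scoring β-catenin peaks that overlapped Smad1 and p300, for which the explant p300 list was used. The groups of peaks named in the closing section, 1 of them drawn in the report, were chosen after their values were seen. Alternatives set at the same time were an overlap of 50% of the shorter peak, summits within 200 bp, the higher-scoring part of each list (50% of its peaks), named chromosomes only, circular shifts, draws from the union of the lists, the p300 list of the other tissue and peaks of middle width. The overlap within the peaks of another protein, and the share of peaks on L chromosomes, were added after seeing the data.

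Planned comparisons of foregut with hindgut and of BIO with DMSO were not made, because the lists pool these libraries. Planned analyses of distances to start sites, gene lists, TCF/LEF and SMAD motifs, densities per Mb on L and S chromosomes and L and S gene copies need a genome or annotation of the same build and were not run. A table of genes of a RefSeq annotation was at hand. It reached over 1 Mb beyond the last peak on 18 of 18 chromosomes, so it was taken to be of another build and was not used for positions.

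The overlap test was tested on simulated lists with the real widths and numbers of peaks. With peaks placed at random, the fold was between 0.941 and 1.10 in the 4 comparisons, and the permutation p was lowest, at 0.0495, for β-catenin with Smad1. With 30% of the peaks put on peaks of the other list, 100% of these were found. They were centred on summits of that list, so this result was fixed in advance and checks only the counting. The other simulated peaks were placed as in the test itself, so sites that cluster were not simulated. A simulated odds ratio of 4 was recovered as 3.97 (interval 3.67 to 4.30) over 16303 peaks by the stratified test. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.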

Results

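Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in Xenopus laevis embryos at Nieuwkoop-Faber stage 20, with antibodies against β-catenin, Smad1 and p300. β-catenin is the transcriptional effector of canonical Wnt signalling and reaches DNA through partner proteins such as TCF/LEF factors. Smad1 is a DNA-binding effector of BMP signalling, and p300 is a histone acetyltransferase commonly used as a mark of active enhancers. The 20 samples were 10 ChIP libraries and 10 input libraries, with 1 library in each group. Smad1 and p300 were profiled in whole embryos, in 2 ChIP libraries. β-catenin and p300 were each profiled in 4 ChIP libraries of foregut and hindgut explants, with DMSO vehicle or with 60 μM BIO, a GSK3 inhibitor that activates Wnt signalling, applied from stage 12 to stage 20. The question named by the series is how Wnt/β-catenin and BMP/Smad1 inputs meet on the genome of foregut and hindgut progenitors.

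The data were 4 peak lists. The explant β-catenin list held 16303 peaks with a median width of 516 bp and a median fold enrichment of 12.1. The whole-embryo Smad1 list held 7976 peaks (median width 383 bp, median fold 8.31), and the explant p300 list held 15146 peaks (median width 411 bp, median fold 8.04). The whole-embryo p300 list held 4555 peaks, the narrowest of the 4 lists, with a median width of 118 bp and a median fold of 5.41. Scores and folds are the authors' values for each peak and were compared only within a list. Each list was 1 call set with no replicate list to set beside it, and read depth is unknown. The titles of 3 lists name IDR, and the Smad1 peak names name a pooled experiment. What was compared by IDR or pooled for Smad1 is not given in the sources used here. The explant lists pool foregut with hindgut and DMSO with BIO by their peak names, so that tissue and treatment could not be compared. Intervals and p-values below therefore describe these lists and measure neither biological nor technical variation between samples.

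The peaks with the highest scores differed between the lists. The strongest β-catenin peak lay on Scaffold62 from 640508 to 641531 (50.4-fold enrichment) and overlapped p300 in both tissues but not Smad1. The next, on chromosome 4L from 130282956 to 130284347 (46.7-fold), overlapped none of the other lists, and the third-ranked, on chromosome 5S from 61738477 to 61739096 (39.9-fold), overlapped both p300 lists. The strongest Smad1 peaks, on chromosome 3S from 33505988 to 33507149 (42.3-fold) and on chromosome 8L from 72101918 to 72103000 (46.6-fold), overlapped β-catenin and both p300 lists. The Smad1 peak that ranked next lay at the start of an unplaced sequence, Scaffold32528, from 43 to 361 (46.4-fold), and overlapped no other list. The leading explant p300 peaks were on chromosome 1S from 125150208 to 125150693 (25.3-fold), chromosome 1L from 151458579 to 151459001 (24.5-fold) and chromosome 3L from 79749242 to 79750013 (24.3-fold). All 3 overlapped whole-embryo p300 and neither β-catenin nor Smad1. The 3 highest whole-embryo p300 peaks lay together on Scaffold20 between 1315746 and 1319019, with 41.5-fold, 38.8-fold and 34.8-fold enrichment, and overlapped no other list. No gene is named for these positions, because the genome build of the lists is not given in the sources used here.

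β-catenin and Smad1 peaks overlapped at many sites, although the lists came from different tissues. The labels give no treatment for the whole-embryo Smad1 library, whereas the β-catenin list pools DMSO and BIO explants. An overlap of peaks, here and below, therefore does not show binding in the same cells or under the same treatment. Of the 7976 Smad1 peaks, 5035 (63.1%, exact 95% interval 62.1 to 64.2) overlapped a β-catenin peak by at least 1 bp. Of the 16303 β-catenin peaks, 4991 (30.6%, interval 29.9 to 31.3) overlapped a Smad1 peak. At these shared sites the summits were a median of 26 bp apart, and 74.0% lay within 50 bp of each other. Random placement of the β-catenin peaks on the same chromosome or scaffold gave a mean of 114.7 overlapping peaks (SD 6.67, 1000 placements), so that the observed overlap was 43.5 times that mean (one-sided permutation p = 0.001, the smallest these placements can give). Random placement takes no account of accessible chromatin or of sequence to which reads cannot be mapped. The excess and its p, here and in the comparisons below, therefore do not show that the proteins bind together. The fold depended on where peaks were allowed to fall. It was 100.3 on named chromosomes alone, 1.11 when peaks were drawn from the union of the lists, and 2.03 within the explant p300 peaks, a setting chosen after seeing the data.

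**Figure D1:**
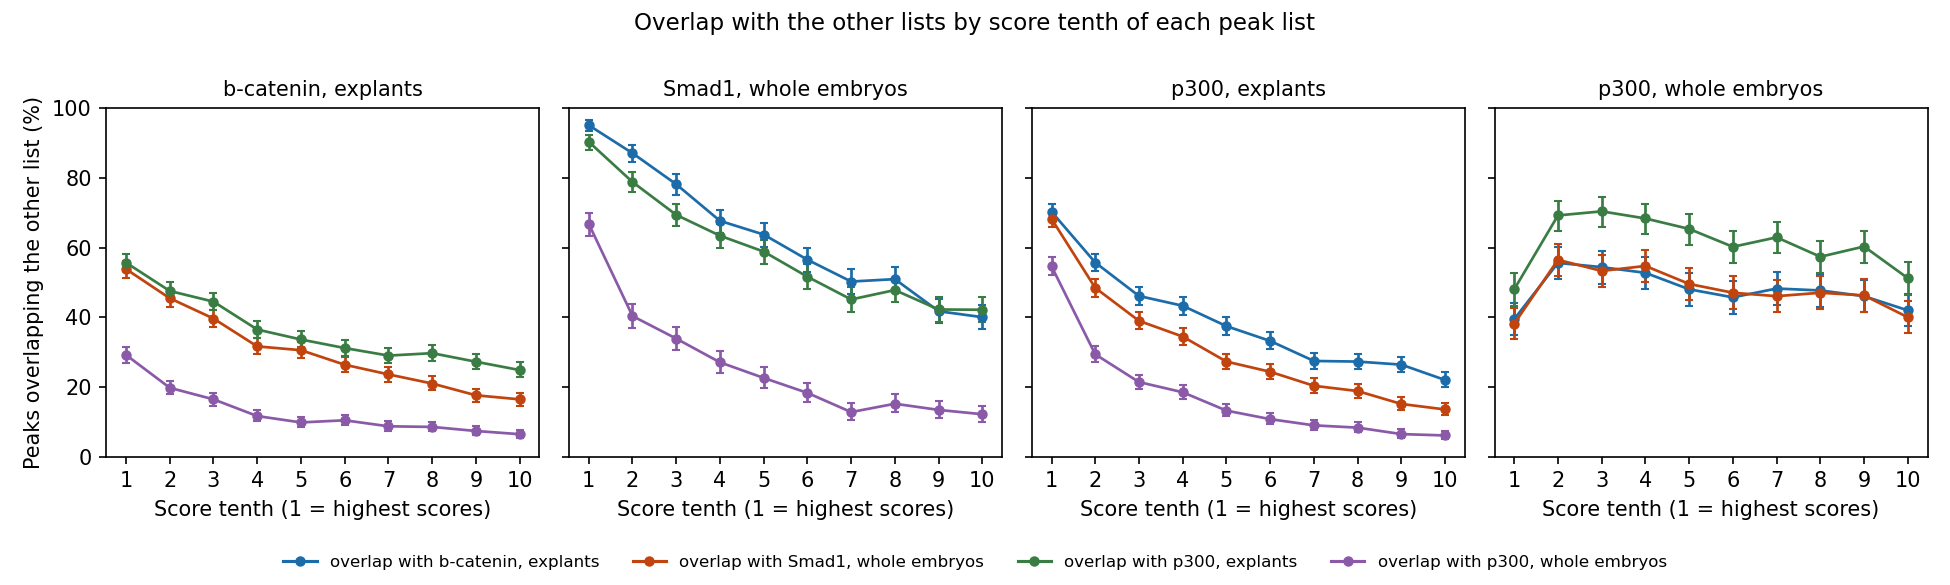
Percent of peaks of each list that overlap each other list by at least 1 bp (y axis), in 10 score classes of equal size within the list (x axis, 1 for the highest scores). Points are shares with exact 95% binomial intervals. Smad1 overlap with β-catenin falls from 95.1% to 40.0%, whereas whole-embryo p300 overlap with explant p300 is lower in the top class (48.0%) than in the next (69.2%).

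β-catenin and Smad1 peaks with higher scores overlapped each other more often than those with lower scores. Among the Smad1 peaks in the top 10% by score, 759 of 798 (95.1%, interval 93.4 to 96.5) overlapped β-catenin, against 319 of 797 (40.0%, interval 36.6 to 43.5) in the lowest 10%. Among β-catenin peaks the corresponding shares with Smad1 were 53.8% (interval 51.4 to 56.3) and 16.4% (interval 14.7 to 18.3). Of the 100 Smad1 peaks with the highest scores, 99 overlapped β-catenin and 97 overlapped explant p300. Of the 100 β-catenin peaks with the highest scores, 40 overlapped Smad1, 55 overlapped explant p300 and 44 overlapped neither. The overlap with Smad1 was thus lower at the very top of the β-catenin list than the 53.8% of its top 10%. In a randomly chosen pair, the Smad1 peak with β-catenin had the higher score with a probability of 0.720 over the Smad1 peak without it (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Its median fold enrichment was 9.02 against 7.63. For β-catenin peaks with against without Smad1 the probability was 0.655 (two-sided permutation p = 1e-05, again the smallest possible), but the median fold differed little, at 12.7 against 11.97. Peaks with a partner were also wider (median 584 against 485 bp for β-catenin, 403 against 352 bp for Smad1).

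p300 was found at a part of the β-catenin sites in explants. Of the 16303 β-catenin peaks, 5865 (36%, interval 35.2 to 36.7) overlapped an explant p300 peak, and 5895 of the 15146 explant p300 peaks (38.9%, interval 38.1 to 39.7) overlapped β-catenin. Summits at these sites were a median of 29 bp apart. Random placement gave a mean of 183.7 overlapping peaks (SD 9.97), for a 31.9-fold excess (one-sided permutation p = 0.001, the smallest possible). The fold was 60.4 on named chromosomes alone and 1.25 within Smad1 peaks, a setting chosen after seeing the data. Against draws from the union of the 4 lists the direction turned, at 0.684-fold, which means that β-catenin and p300 sites coincided less often than if each list had been drawn independently from the union, each region of which is in at least 1 list by construction.

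Whole-embryo Smad1 and p300 also shared sites. Of the 7976 Smad1 peaks, 2094 (26.3%, interval 25.3 to 27.2) overlapped a whole-embryo p300 peak, and 2180 of the 4555 whole-embryo p300 peaks (47.9%, interval 46.4 to 49.3) overlapped Smad1. Random placement gave a mean of 29.6 overlapping peaks (SD 3.01), for a 70.7-fold excess (one-sided permutation p = 0.001, the smallest possible). More Smad1 peaks, 4704 or 59.0% (interval 57.9 to 60.1), overlapped the longer explant p300 list. The fold for whole embryos was 287 on named chromosomes alone, 1.71 against draws from the union and 2.63 within β-catenin peaks, the last of these settings chosen after seeing the data.

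β-catenin peaks that overlapped a Smad1 peak also overlapped p300 far more often than β-catenin peaks without Smad1. Explant p300 was present at 3690 of the 4991 β-catenin peaks with Smad1 (73.9%, interval 72.7 to 75.1) and at 2175 of the 11312 β-catenin peaks without Smad1 (19.2%, interval 18.5 to 20.0). The odds ratio was 11.9 (95% interval 11.01 to 12.9), and the two-sided Fisher's exact test gave a p below the smallest number the software holds. With the whole-embryo p300 list the shares were 33.8% and 3.59%, with an odds ratio of 13.7 (interval 12.2 to 15.4). A majority of the β-catenin peaks, 9006 or 55.2% (interval 54.5 to 56.0), overlapped neither Smad1 nor either p300 list.

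**Figure D2:**
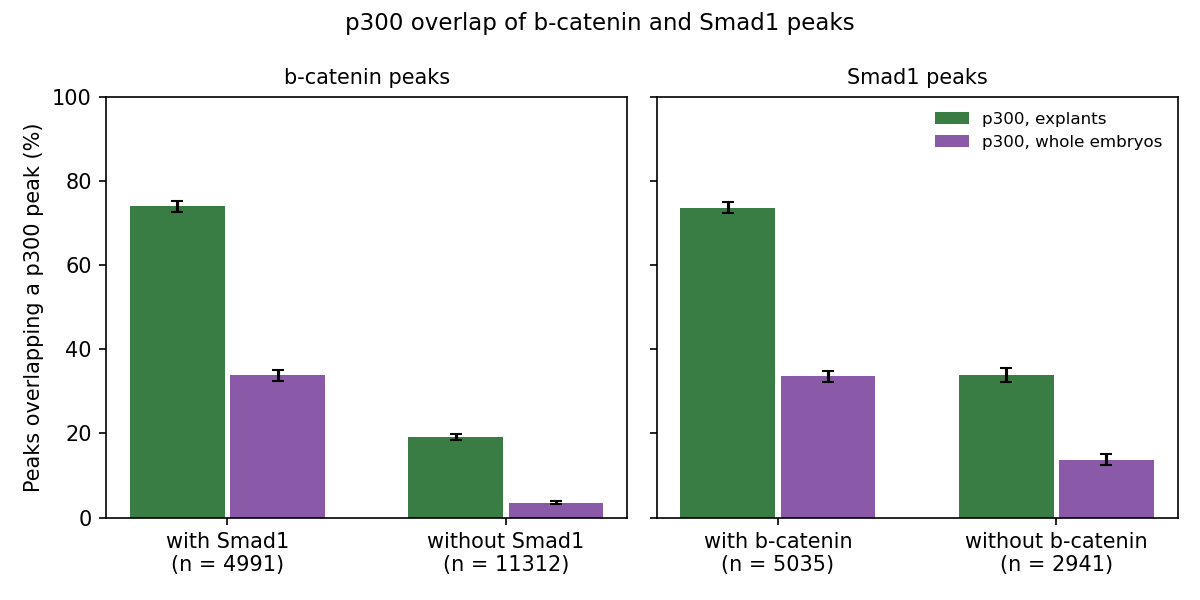
Percent of β-catenin peaks (left) and Smad1 peaks (right) that overlap a p300 peak, for peaks with and without the other factor, with explant p300 in green and whole-embryo p300 in purple. Bars are shares with exact 95% binomial intervals, and p300 overlap is higher in each case where the other factor is present, as in 73.9% against 19.2% of β-catenin peaks with explant p300.

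The same held for Smad1 sites, with a smaller contrast. Whole-embryo p300 was present at 1689 of the 5035 Smad1 peaks with β-catenin (33.5%, interval 32.2 to 34.9) and at 405 of the 2941 without it (13.8%, interval 12.5 to 15.1). The odds ratio was 3.16 (95% interval 2.80 to 3.56; two-sided Fisher's exact test, p = 3.6e-89). With explant p300 the odds ratio was 5.44 (interval 4.93 to 6.01), from shares of 73.6% and 33.9%.

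The 10 β-catenin peaks with the highest scores that overlapped both Smad1 and explant p300 had folds of 25.7 to 38.1 for β-catenin. On chromosome 5L from 123040630 to 123041401, all 3 proteins were strongly enriched, at 38.1-fold for β-catenin, 27.3-fold for Smad1 and 15.6-fold for explant p300, with the Smad1 and p300 summits 16 and 31 bp from the β-catenin summit. A site on chromosome 6S from 13925691 to 13926681 had 30.2-fold, 19.5-fold and 14.0-fold enrichment, and a site on chromosome 8S from 37836478 to 37837216 had 26.6-fold, 17.0-fold and 16.9-fold enrichment. At the other sites the Smad1 fold was lower than at these, and lay on either side of the Smad1 list's median of 8.31. The highest-scoring of the 10, on chromosome 8L from 71440947 to 71441409, had 36.7-fold β-catenin enrichment with 9.95-fold Smad1 and 8.47-fold p300 enrichment. The site on chromosome 6L from 20832197 to 20833792 had 35.4-fold, 5.76-fold and 7.85-fold enrichment, the last from the nearer of the 2 p300 peaks it overlapped. The remaining sites lay on chromosome 1L from 137909082 to 137910758 and from 170091415 to 170092726, on chromosome 9_10L from 40821075 to 40822004, on chromosome 2S from 138345158 to 138345953 and on Scaffold60 from 646699 to 648096.

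**Figure D3:**
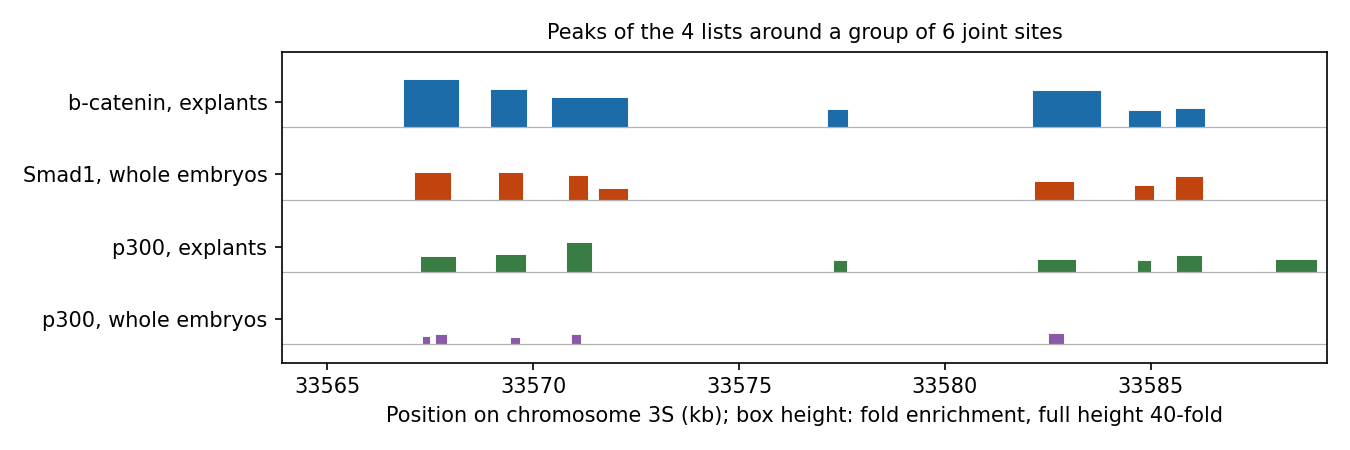
Peaks of the 4 lists (rows) along chromosome 3S around the group of 6 joint sites from 33566900 to 33586291, with 3 kb to either side (x axis in kb). Boxes span each peak, and their height is the fold enrichment on a scale from 0 to 40-fold, with the highest β-catenin peak at 36.6-fold and the highest Smad1 peak at 20.6-fold.

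p300 peaks were partly the same in explants and whole embryos. Of the 4555 whole-embryo p300 peaks, 2794 (61.3%, interval 59.9 to 62.8) overlapped an explant p300 peak, whereas 2692 of the 15146 explant p300 peaks (17.8%, interval 17.2 to 18.4) overlapped a whole-embryo peak. Random placement gave a mean of 63.2 overlapping explant peaks (SD 4.07), for a 42.6-fold excess (one-sided permutation p = 0.001, the smallest possible). The fold was 180 on named chromosomes alone, 1.15 against draws from the union and 2.36 within β-catenin peaks, the last chosen after seeing the data. The lists differed in length and in how they were thresholded, so that a p300 site in a single list is not shown to be specific to that tissue.

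Over all lists, the peaks merged into 28769 regions, of which 19670 were in 1 list and 1503 were in all 4. Xenopus laevis is allotetraploid, with a long (L) and a short (S) copy of each chromosome. Of peaks on named chromosomes, 59.8% of β-catenin (interval 59.0 to 60.6), 59.6% of Smad1 (interval 58.4 to 60.7), 60.3% of explant p300 (interval 59.5 to 61.1) and 57.6% of whole-embryo p300 peaks (interval 56.1 to 59.1) lay on L chromosomes. The L chromosomes made up 54.6% of the span between the chromosome starts and the last peak, so that the share on L was above that of the span in each list.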

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

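The tests of differences in this part were chosen after the odds ratios were seen. The association of p300 with the overlap of β-catenin and Smad1 peaks differed between the 2 p300 lists. These lists differ in tissue and also in length, peak width and threshold. At Smad1 peaks, the odds ratio for p300 with against without β-catenin was 1.72 times as high with explant p300 as with whole-embryo p300 (bootstrap 95% interval 1.5 to 1.98, 2000 resamples of peaks). The ratio of the shares with p300 went the other way, at 2.17 with explant p300 and 2.44 with whole-embryo p300, but with an explant list matched to the whole-embryo list in length and width it was 3.42, or 1.40 times the whole-embryo value (interval 1.24 to 1.59). At β-catenin peaks, the odds ratio with against without Smad1 was 0.869 times as high with explant p300 (interval 0.771 to 0.983), and the ratio of shares was 3.85 with explant and 9.41 with whole-embryo p300. With the matched list, the difference in odds ratio at β-catenin peaks was no longer separated from 1 (0.897, interval 0.790 to 1.03), whereas the ratio of shares, at 7.74, was 0.823 times the whole-embryo value (interval 0.736 to 0.924).

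For Smad1 peaks, 2 technical explanations were tested. If the whole-embryo list were only shorter, by its weaker sites, and narrower, an explant list of its 4555 highest scores at 118 bp around the summit would give a similar odds ratio, but it was still 1.59 times as high (interval 1.37 to 1.84). If the whole-embryo list missed p300 sites at random, Smad1 peaks with strong and weak explant p300 would be found in it equally often, but 50.1% of the stronger 2352 and 24.4% of the weaker 2352 were, a ratio of 2.05 (interval 1.89 to 2.23). Sites missed evenly would lower an odds ratio above 1 while the ratio of shares stayed the same. The test therefore shows only that the loss depended on the explant score, not that missing sites left the odds ratio unchanged. Loss of weaker sites without a sharp limit was not tested and stays open. Tissue and the thresholds of the lists stay open too, as untested.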

How the results depend on the processing

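The settings within the peaks of another protein and the shares on L chromosomes were chosen after seeing the data. Of 52 alternatives, 50 kept the direction and the side of the threshold, or stayed within the interval of the share. With this many peaks, values close to 1 also passed the threshold. The overlap of β-catenin with Smad1 counts as kept, although its fold was 43.5 in the main setting and 1.11 within the union. The count therefore says little about the size of the values. The overlap of β-catenin with explant p300 turned to 0.684 when both lists were compared within the union of the lists. Each region of the union is in at least 1 list by construction, which lowers this value for long lists. The share of explant p300 peaks on L chromosomes moved from 60.3% to 61.3% in the higher-scoring part of the list. This lies outside the interval of the full list (59.5 to 61.1). The interval of the higher-scoring part, 60.1 to 62.4, holds 60.3%, so the shift is within its counting error. The odds ratio for p300 ran from 9.33 to 13.7 over the alternatives at β-catenin peaks and from 2.68 to 5.44 at Smad1 peaks, and the score comparisons from 0.645 to 0.657 and from 0.7001 to 0.721. The folds of the overlaps moved most and depend on the set of places allowed. For Smad1 with whole-embryo p300 the fold was 1.71 against draws from the union. Over random placements it ran from 67.9 with circular shifts to 287 on named chromosomes alone. No paired analysis was possible because the deposited lists pool the DMSO and BIO libraries. Settings chosen beforehand for start sites, motifs, gene lists, gene copies and densities per Mb were not run, since they need a genome or annotation of the build. The end of the lists limits what an absent overlap means. In the weakest 10% of the explant p300 list, 22.0% of 1514 peaks overlapped β-catenin (interval 19.9 to 24.2), against 0.868% of random placements. A complete list would also overlap above chance to its end, so this does not show whether p300 sites are missing from the list, and that stays open.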

Other observations

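The grouping of joint sites, the crowding of whole-embryo p300 peaks, the proximity of peaks and the enrichment of p300 by class were tested only after related results had been seen. In the explant list, p300 was more enriched where β-catenin and Smad1 peaks were both present. Folds of whole-embryo p300 were not compared by class. Explant p300 peaks with both had a median fold of 9.20 (3697 peaks), against 7.97 with β-catenin alone (2198 peaks), 8.24 with Smad1 alone (992 peaks) and 7.72 with neither (8259 peaks). In a random pair, the peak with both had the higher fold than the peak with neither with a probability of 0.675 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). For β-catenin peaks the order depended on the measure. The median fold was 10.7 at the 2175 peaks with p300 and without Smad1, 11.9 at the 1301 with Smad1 and without p300, 12.2 at the 9137 with neither and 12.9 at the 3690 with both. The median scores of these classes were 1186, 1324, 1170 and 1731.

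Joint sites, meaning β-catenin peaks with Smad1 and explant p300, lay near another joint site more often than randomly drawn β-catenin peaks, although most stood alone. At a gap of up to 10 kb the 3690 joint sites gave 2983 positions, of which 2461 were single sites and 37 were groups of at least 4. Groups of 6 were found on chromosome 3S from 33566900 to 33586291, chromosome 3L from 110790927 to 110810605, chromosome 7S from 16926816 to 16940033 and chromosome 7L from 21854059 to 21875411, among 8 groups of that size named here after their values were seen. The hypothesis that joint sites gather in loci beyond the grouping of β-catenin peaks was tested by drawing as many β-catenin peaks at random. Another joint site within 10 kb was found for 33.3% of joint sites, against a mean of 14.4% and a highest value of 17.0% in 1000 draws. With draws matched on score the mean was 16.7% and the highest value 19.1%. Draws from β-catenin peaks with Smad1 or p300 alone were not made, so grouping of Smad1 or p300 peaks by themselves stays open. β-catenin peaks without an overlapping Smad1 peak also lay near Smad1 more often than random placements: 20.7% (interval 20.0 to 21.5) were within 10 kb, against 4.52%.

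The higher share of p300 at β-catenin peaks with Smad1 was weighed against 2 technical explanations, with tests set before their results were seen. If stronger and wider peaks overlapped every list more often and this were the whole cause, the odds ratio would reach 1 within classes of score and width, but it was 10.4 (95% interval 9.61 to 11.3) over 30 such classes. If scaffolds of uncertain copy number were the cause, it would reach 1 on named chromosomes, but it was 11.8 (interval 10.8 to 12.7). Scaffolds held only 6.25% of the β-catenin peaks, so leaving them out could hardly have brought the odds ratio to 1. The value shows only that scaffold peaks did not make the ratio. Uncertain copy number on named chromosomes was not tested and stays open. Accessible chromatin that is enriched in any ChIP was not tested and stays open, since no list of another kind was analysed here.

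The strongest whole-embryo p300 peaks stood apart. Of the 456 peaks in the top 10% by score, 48.0% were in the explant p300 list, against 69.2% of the next 10%, and 225 overlapped no other list. On chromosome 5S between 81719243 and 81732583, 20 whole-embryo p300 peaks with up to 23.5-fold enrichment lay within 13.3 kb, and none overlapped another list. Groups of 6 such peaks on Scaffold20 and of 4 on chromosome 8L between 2930164 and 2938690 likewise overlapped none. The other 9 of the 12 groups of at least 4 whole-embryo p300 peaks did overlap explant p300, such as that on chromosome 9_10L between 13492584 and 13499157 with 3 of its 4 peaks. These groups were named after their values were seen. If noise among weak peaks were the cause of the incomplete overlap, the strongest 20% would be found in the explant list much more often than the weakest 20%, but the ratio of their shares was 1.05 (interval 0.967 to 1.14). This ratio includes the low top 10%. Below it the share fell from 70.4% in the class ranked 3 of 10 to 51.2% in the weakest 10%, so noise may account for part of the missing overlap at weak peaks. If crowded peaks or scaffolds, as collapsed repeats would give, were the whole cause of the low share in the top 10%, it would recover without them, but it was 51.1% (interval 44.9 to 57.3) against 66.0% in the next 10%. Among the peaks taken out, the shares were 43.8% in the top 10% and 76.9% in the next 10%, so the filter also removed peaks often found in explants. Isolated peaks from collapsed repeats on named chromosomes would pass the filter and were not tested. They stay open, as do tissue and the differing thresholds of the lists, which are untested too.

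A hypothesis that peak density follows a shared order of sequence on the L and S copies of a chromosome was tested on the merged regions in 50 equal parts of each chromosome. The median Spearman correlation of the 9 L and S pairs was 0.299, against a median of 0.00353 over all 362880 re-pairings of L with S chromosomes (one-sided exact permutation p = 0.000579; 0.0019 after Benjamini-Hochberg adjustment over 5 sets of peaks). In the 4 single lists the median was lower. It was 0.203 for β-catenin, 0.212 for Smad1, 0.233 for explant p300 and 0.143 for whole-embryo p300. The adjusted p of the same test was highest for Smad1 and whole-embryo p300, at 0.0268 for each. In the merged regions the pairs differed, from 0.586 for chromosome 5 and 0.555 for chromosome 6 to −0.331 for chromosome 8, and 4 of the 9 L chromosomes correlated best with their own S copy. Chromosome 8L reached 0.392 with another S chromosome. With the order of the S copy turned around, a comparison made after seeing the negative value, the correlation was lower in 6 of the 9 pairs, such as −0.174 for chromosome 1 and 0.0118 for chromosome 5. It was higher in 3, at 0.274 for chromosome 8, 0.279 against 0.155 for chromosome 4 and −0.0314 against −0.0746 for chromosome 2.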
